A study of Danio rerio with 5 samples.

How the data were processed

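Total RNA came from zebrafish embryos (Tübingen strain) freed of chorion and yolk. It was collected at 4 hours post-fertilisation (hpf), called here MBT for the mid-blastula transition, and at 5.3 hpf, called post-MBT. Per the labels' protocols, 5 ng of DNase-treated total RNA per library was reverse-transcribed with random hexamers, cut and tagged by a transposase, and amplified over 10 PCR cycles. The labels name no poly(A) selection or removal of ribosomal RNA, and the counts carry no strand, so reads of a gene and of a gene overlapping it on the other strand cannot be told apart. There were 3 MBT and 2 post-MBT libraries. Nothing in the labels says whether the libraries of a stage came from separate clutches, so p-values measure the spread between these libraries, which can be partly technical.

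The submitters' processing notes name Novoalign 2.8 and DESeq2. The deposited table holds 22656 genes with whole-number counts per library, per the file headers, and coordinates on the build D_rerio_Sep_2014 with RefSeq-style gene models. Gene starts in that table count from 0 and are given here from 1. The table also gives, per the file headers, the authors' log2 ratio of 4 hpf over 5.3 hpf from DESeq2. The deposited score values are, per the file headers, the negative log10 of a corrected p-value times 10. It further holds the exonic length of each gene and a comparison of exon counts within each gene, with its own log2 difference and score, from a chi-square test with Bonferroni correction. How reads mapping to several places were counted is not given in the sources used here, so genes with near-identical copies (the miR-430 genes, histone genes and the repeated genes of chromosome 4) carry uncertain values. A further 10 columns of per-library values (the authors' FPKM and regularised log values) were not used. The count columns name the stage but not which sample of that stage they belong to. The libraries are therefore called MBT A, B and C and post-MBT A and B, and were used as replicates of their stage.

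Counts summed to 2488983, 3641226, 2781303, 3701401 and 3204831 in MBT A, B and C and post-MBT A and B. The relative sampling error of a count is 10.0% at 100 counts and 31.6% at 10 counts. A count of 0 allows up to 3 counts, which is 1.08, 0.688, 1.05, 0.966 and 1.11 CPM in the libraries in that order. Intervals and floors cover counting error only, because PCR copies are not independent molecules. Within a stage, all replicate pairs differed by more than sampling noise (chi-square per degree of freedom of 1.27 to 1.92), so each library counted as 1 replicate.

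Changes between the stages were tested with edgeR 4.0.16 (R 4.3.3; filterByExpr with its count minimum of 10, TMM factors, robust quasi-likelihood test). P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Log2 fold changes are post-MBT over MBT, given ± SE, and levels are CPM (counts divided by the product of the library's count over the tested genes and its TMM factor, on a common scale), given as mean ± SD. Gene lists fixed before the data were examined were tested against all other genes with camera (limma 3.58.1, preset correlation 0.01). Lists needed at least 5 tested members. Camera was run again with an estimated correlation. The lists were also tested with fry, which does not compare a list with other genes. Of the 21 lists, 20 had enough tested members. Some genes belong to several lists. The result of 1 list, and the name of 1 member of another, are not reported here. Chromosomes were compared by 2-sided Fisher's exact tests over 54 region and direction pairs. Genomic span and exonic length were compared by 2-sided permutation tests of the difference in medians with 100000 resamples, whose smallest possible p is 1e-05 (Python 3.11.15, scipy 1.17.1, numpy 2.4.6). Counting every way to split 5 libraries into 3 and 2 gives 10 splits, so an exact test of a single value cannot go below p = 0.1.

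The genes named follow a rule fixed at the same time as the lists. They are smarca4a and smarca2, the 8 largest rises and 8 largest falls, and the 4 members of each list with the smallest adjusted p. A large rise or fall needed an adjusted p under 0.05, libraries that do not overlap between the stages and a mean of at least 50 counts per library, and clone or locus names were skipped. Members that moved against their list, genes with no count in one stage, and the genes of the exon comparison are also named and were chosen after their values were seen.

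On counts simulated for this comparison (11490 genes), the edgeR test called 9 of 47 planted changes of 1.25-fold, 16 of 47 of 1.5-fold, 39 of 49 of 2-fold and 44 of 47 of 4-fold, and called 6 unchanged genes. It made 114 calls there against 7537 in the real data, so these shares need not carry over. A list planted at 1.5-fold was called by camera, and no list was called with none planted. Simulated genes varied independently and shared 1 dispersion, so this does not show how camera does on lists whose members vary together. The chromosome, span and pair tests were tried on random calls, shortened spans and random pair values, not on simulated counts. Genes were independent there, so near-identical copies were not covered. The alternatives were DESeq2 size factors, library totals, upper-quartile factors, no filter and a filter at a mean of 50 counts, thinning to the smallest library, an offset for exonic length, a replicate block, each library left out in turn, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) computed from the counts, the DESeq2 1.42.0 Wald test, and stricter calls. Where 1 post-MBT library was left out, the remaining library was assumed to vary like the MBT ones. Leaving out the 15 mitochondrial genes and the genes spanning over 1 Mb was added after seeing the data.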

Results

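Total RNA was sequenced from zebrafish embryos at the mid-blastula transition (MBT, 4 hpf, sphere stage; n = 3 libraries) and after it (post-MBT, 5.3 hpf, 30% epiboly; n = 2 libraries). At the MBT the embryo starts to transcribe its own genome in bulk while maternal transcripts are still abundant, and at 5.3 hpf epiboly is under way shortly before gastrulation. The total count per library was 2488983, 3641226, 2781303, 3701401 and 3204831 in MBT A, B and C and post-MBT A and B. Mitochondrial ribosomal RNA took 44.1% (44.1 to 44.2%), 40.2% (40.1 to 40.2%), 48.0% (48.0 to 48.1%), 48.5% (48.4 to 48.5%) and 48.6% (48.5 to 48.6%) of the counts in that order (95% Wilson intervals), and nuclear genes held 1329104, 2075880, 1374662, 1800872 and 1554414 counts. Levels below are mean CPM ± SD over n = 3 MBT and n = 2 post-MBT libraries, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

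The first comparison addressed how the transcriptome differed between the stages. Of 12007 tested genes, 3724 rose and 3813 fell. At a change of at least 2-fold, 1919 rose and 2233 fell. Patterning and segmentation genes were among the largest rises. The somite clock genes her7 and her1 rose from 0.466 ± 0.193 to 62.8 ± 3.64 CPM and from 1.01 ± 0.518 to 69.5 ± 7.84 CPM. The endoderm and heart regulator gata5 rose from 0.505 ± 0.173 to 50.4 ± 4.87 CPM, the ventral signal bmp4 from 0.665 ± 0.411 to 47.0 ± 4.52 CPM, and the mesoderm regulator ta (brachyury; chromosome 19, 14325345 to 14329397) from 8.91 ± 1.76 to 412 ± 32.2 CPM. The protocadherin gene pcdh8 rose from 2.27 ± 0.977 to 107 ± 2.35 CPM, the kinesin gene kif26ab from 0.816 ± 0.521 to 42.8 ± 3.72 CPM and the apolipoprotein gene apoc1l from 1.74 ± 0.903 to 70.4 ± 3.36 CPM.

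The largest falls included the claudin gene cldng, from 52.8 ± 7.61 to 4.38 ± 2.0 CPM, and the deadenylation factor gene btg4, from 38.1 ± 4.81 to 4.67 ± 0.229 CPM. The Frizzled receptor gene fzd5 fell from 24.9 ± 4.71 to 2.30 ± 2.21 CPM, the autophagy kinase gene ulk1a from 26.9 ± 4.86 to 2.75 ± 0.209 CPM and aftphb from 35.5 ± 3.09 to 3.74 ± 1.08 CPM. Genes of miR-430, the microRNA that clears maternal transcripts, also fell: mir430c-2 from 36.3 ± 4.91 to 2.98 ± 1.03 CPM, mir430a-3 from 34.6 ± 9.83 to 4.19 ± 0.912 CPM and mir430b-1 from 57.3 ± 8.39 to 7.15 ± 1.46 CPM. The copies of miR-430 are near-identical, so the value of each single copy is uncertain. Among these 16 genes, adjusted p ranged from 1.73e-54 (ta) to 7.64e-15 (fzd5), and libraries that do not overlap between the stages were part of the rule that chose them. Over all tested genes the libraries did not overlap in 73.9%, where chance gives 20% for 3 against 2. The first principal component held 90.1% of the variance and separated the stages. With library totals in place of TMM factors, the median log2 fold change of all tested genes dropped by 0.41, and 2173 genes rose and 5574 fell. Changes below are relative to the TMM scale unless another is named.

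**Figure D1:**
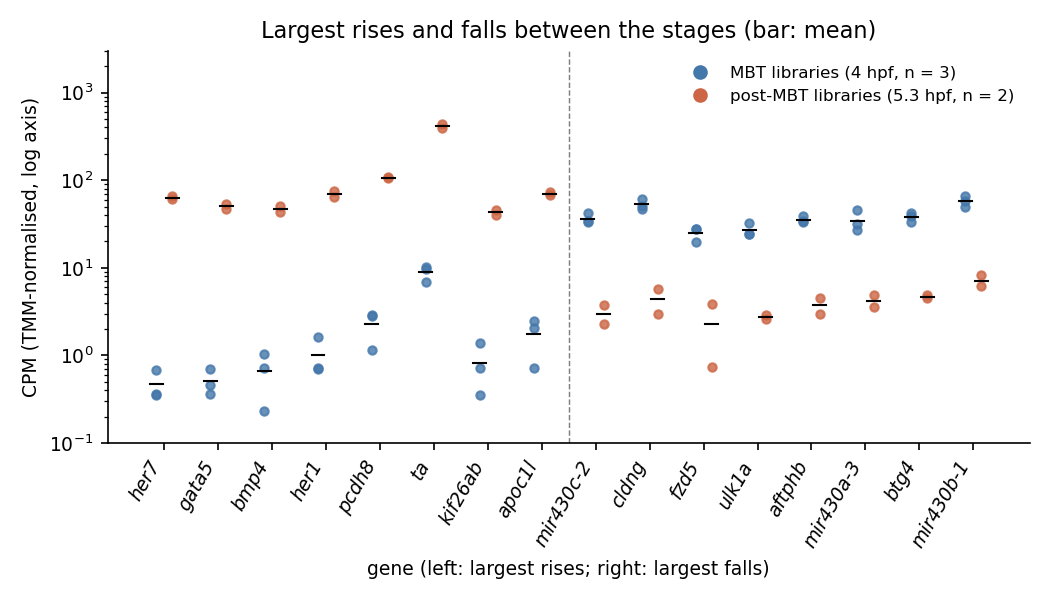
Per-library TMM-normalised CPM (log axis) of the 8 genes with the largest rises and the 8 with the largest falls; dots are single libraries (blue, 3 MBT; orange, 2 post-MBT) and bars are means. Genes were chosen among those with no overlap between the 2 sets of dots, and ta goes from 8.91 ± 1.76 to 412 ± 32.2 CPM.

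The series is about the SWI/SNF remodeling ATPases Brg1 and Brm, so the levels of their genes were compared. The Brg1 gene smarca4a (chromosome 3, 19096050 to 19132138) rose from 268 ± 14.6 to 436 ± 9.0 CPM, a log2 fold change of 0.70 ± 0.07 (adjusted p = 8.64e-14). The Brm gene smarca2 (chromosome 5, 44538778 to 44683990) fell from 78.1 ± 7.74 to 39.9 ± 5.96 CPM, a log2 fold change of -0.95 ± 0.13 (adjusted p = 1.43e-09). There were 3.45 ± 0.155 counts of smarca4a per count of smarca2 at the MBT (SD, n = 3) and 11 ± 1.42 after it (SD, n = 2). The 2-sided exact permutation p for this ratio was 0.1, the smallest that 10 splits allow. With library totals the log2 fold change of smarca4a was 0.29 and that of smarca2 was -1.37, both still called. With limma-trend on log2(FPKM + 1) they were 0.29 and -1.23.

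**Figure D2:**
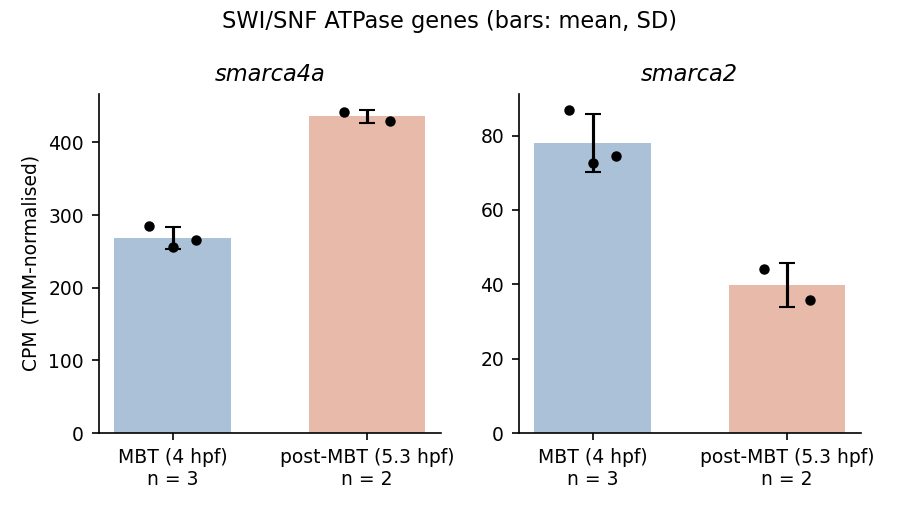
TMM-normalised CPM of smarca4a and smarca2; bars are stage means, error bars are SD and dots are libraries (3 MBT, 2 post-MBT). The smarca4a bars stand at 268 and 436 CPM and the smarca2 bars at 78.1 and 39.9 CPM.

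Subunits of the SWI/SNF complexes (BAF and PBAF) moved in both directions. Of 28 tested genes, 16 rose, 6 fell and 6 had no call (camera adjusted p = 0.0174; adjusted p = 0.133 with an estimated correlation). The 4 with the smallest adjusted p were smarcd1, with a log2 fold change of 0.93 ± 0.08, actl6a (1.03 ± 0.11), pbrm1l (0.76 ± 0.08) and smarcc1a (0.72 ± 0.07), which encode core or PBAF subunits. Besides smarca2, the falls were smarcc2, with a log2 fold change of -2.83 ± 0.49, pbrm1 (-1.46 ± 0.49), smarcc1b (-1.23 ± 0.19), arid1b (-0.52 ± 0.17) and bcl7ba (-0.33 ± 0.12). With the DESeq2 Wald test 15 of 29 rose and 3 fell, and pbrm1, arid1b and bcl7ba lost their call there and without post-MBT A. With library totals 12 rose and 8 fell, and the list lost its call (camera adjusted p = 0.107, with a range over the alternatives of 0.00196 to 0.107; median 0.07). Among other ATP-dependent remodelers and their partners, 13 of 18 rose and 3 fell (baz1a, smarcad1 and hells) (camera adjusted p = 2.19e-04; adjusted p = 0.134 with an estimated correlation), though hells lost its call with DESeq2, with the length offset and without post-MBT B. The examples were atrx (1.16 ± 0.07), the CHARGE syndrome gene chd7 (0.97 ± 0.06), srcap (0.81 ± 0.07) and the NuRD ATPase gene chd4b (0.82 ± 0.07). Chromatin modifiers were split, with 13 of 30 up, 8 down and 9 without a call (camera adjusted p = 0.353; adjusted p = 0.489 with an estimated correlation). With library totals 9 were up and 14 down. Within them, the maintenance DNA methyltransferase gene dnmt1 fell from 328 ± 13.3 to 127 ± 2.11 CPM, while hdac1 (1.11 ± 0.07), the Polycomb methyltransferase gene ezh2 (1.11 ± 0.08) and kmt2d (0.85 ± 0.06) rose. Histone genes rose in 12 of 14 cases, and none fell (camera adjusted p = 1.16e-04; adjusted p = 0.112 with an estimated correlation). The examples were h3f3a (1.44 ± 0.09), hist2h3c (1.58 ± 0.11), h2afx (1.17 ± 0.12) and hist1h4l (1.28 ± 0.13), and histone genes share reads with near-identical copies. With the length offset 11 histone genes rose and none fell (camera adjusted p = 0.00957). Their median log2 fold change was then 0.62, against 1.01 without the offset.

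Zygotic and germ-layer genes rose together. Of 28 early zygotic genes 24 rose, 3 fell (her5, irx7 and mxtx2) and 1 had no call (camera adjusted p = 1.92e-19; adjusted p = 0.112 with an estimated correlation). Of these falls her5 was called in every alternative, while irx7 lost its call in 3 of 17 refits and mxtx2 in 10 of 17, the DESeq2 Wald test among them. The T-box gene tbx16 rose from 136 ± 15.4 to 910.0 ± 26.1 CPM, apoeb from 68.8 ± 6.30 to 522 ± 15.6 CPM, zic2b from 135 ± 4.36 to 626 ± 5.84 CPM and the endoderm gene foxa3 from 13.7 ± 0.673 to 175 ± 14.6 CPM. Mesendoderm and organizer genes rose in 26 of 29 cases and 1 (eomesa) fell (camera adjusted p = 3.33e-22; adjusted p = 0.112 with an estimated correlation). Besides ta, tbx16 and foxa3 the leading member was mixl1, which rose from 9.59 ± 1.05 to 203 ± 4.80 CPM. Among ventral BMP and Wnt genes 22 of 23 rose and none fell (camera adjusted p = 5.20e-16; adjusted p = 0.112 with an estimated correlation). The transcriptional repressor genes vent and ved rose from 4.49 ± 0.676 to 117 ± 6.78 CPM and from 17.1 ± 3.59 to 149 ± 5.64 CPM, bambia from 17.6 ± 2.72 to 149 ± 2.25 CPM and wnt11 from 9.73 ± 1.57 to 104 ± 7.34 CPM. In the FGF pathway 9 of 12 rose and 1 (etv5a) fell (camera adjusted p = 9.66e-08; adjusted p = 0.149 with an estimated correlation). The ETS factor gene etv4 rose from 19.4 ± 2.01 to 180.3 ± 5.88 CPM, the feedback phosphatase gene dusp6 from 43.5 ± 5.22 to 217 ± 24.1 CPM, etv5b from 72.0 ± 10.5 to 243 ± 21.2 CPM and fgf8a from 4.71 ± 0.461 to 47.8 ± 2.96 CPM. Neuroectoderm genes rose in 11 of 13 cases, and 2 (her5 and, less surely, irx7) fell (camera adjusted p = 3.26e-07; adjusted p = 0.135 with an estimated correlation). The SoxB1 gene sox3 rose from 67.2 ± 5.47 to 381 ± 19.7 CPM, zic2a from 7.58 ± 1.58 to 62.9 ± 1.19 CPM and sox19a by a log2 fold change of 1.86 ± 0.11.

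Genes of the extraembryonic and moving tissues also rose. Enveloping layer genes, which mark the outer epithelium, rose in 12 of 14 cases and 1 fell (camera adjusted p = 7.82e-12; adjusted p = 0.101 with an estimated correlation). The keratin genes krt8, krt4 and krt18 rose from 34.0 ± 4.87 to 353 ± 2.27 CPM, from 22.7 ± 4.31 to 169 ± 2.28 CPM and from 23.4 ± 3.99 to 138 ± 7.49 CPM, and the envoplakin gene evpla rose from 3.84 ± 1.55 to 140.1 ± 6.39 CPM. The yolk had been removed from the embryos, which can take away part of the yolk syncytial layer. Of its 7 tested genes 5 rose and 1 (mxtx2, not called in most alternatives) fell (camera adjusted p = 0.0226; adjusted p = 0.200 with an estimated correlation). With the offset for exonic length, the list was not called (camera adjusted p = 0.0698; range over the alternatives 0.00254 to 0.0698). The regulator gene hnf4a had no count in the 3 MBT libraries and 78 and 65 counts post-MBT, at least 82.2-fold higher against a floor of 3 counts over the group. The related hnf1ba rose from 1.66 ± 0.904 to 19.0 ± 3.14 CPM and cebpa from 0.462 ± 0.400 to 4.76 ± 1.47 CPM. The transporter gene slc26a1 had 2 counts over the MBT libraries and 47 post-MBT, a ratio of 40.5 (95% exact counting interval 10.6 to 345). Gastrulation movement and adhesion genes rose in 21 of 23 cases and 1 (fn1a) fell (camera adjusted p = 7.85e-11; adjusted p = 0.118 with an estimated correlation). Besides pcdh8 and wnt11, flrt3 rose from 5.57 ± 0.162 to 74.7 ± 5.84 CPM and the glypican gene gpc4 from 27.4 ± 2.58 to 97 ± 6.47 CPM. In all lists with a member at 0 in the MBT libraries (enveloping layer, FGF, yolk syncytial layer), the median stayed the same with that member at its bound.

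**Figure D3:**
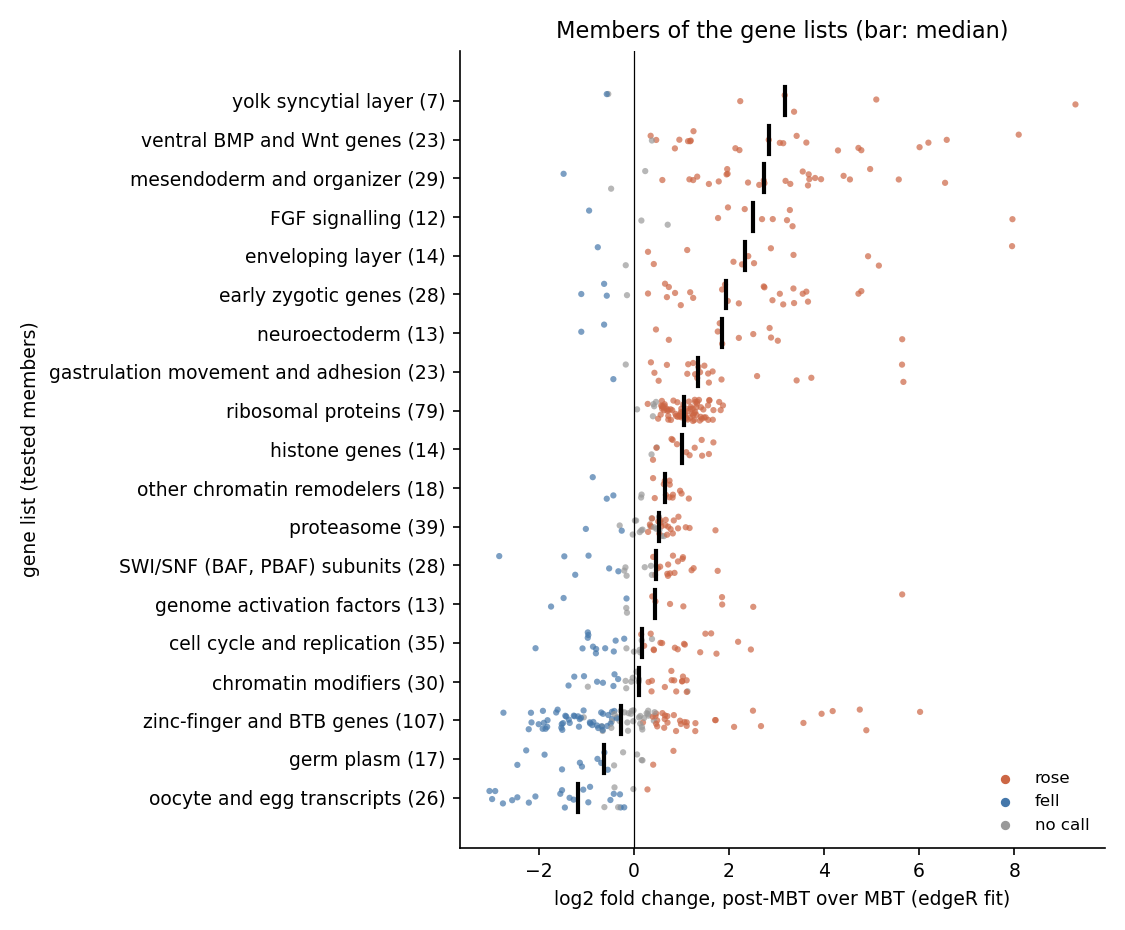
Log2 fold change (post-MBT over MBT) of each tested member of 19 gene lists; dots are genes, coloured by call, black bars are list medians and the number of tested members is in brackets. Medians run from -1.16 for oocyte and egg transcripts to 3.17 for yolk syncytial layer genes.

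Most oocyte and egg transcripts in their list fell. Of 26 oocyte and egg transcripts 21 fell, 1 (zgc:56699) rose and 4 had no call (camera adjusted p = 1.13e-08; adjusted p = 0.101 with an estimated correlation). No member was called up with library totals, with the length offset or with DESeq2. Besides btg4, the Balbiani body gene buc fell from 205 ± 6.40 to 37.7 ± 6.02 CPM, mid1ip1l from 147 ± 9.04 to 21.8 ± 1.72 CPM, cth1 from 331 ± 15.6 to 121 ± 0.644 CPM and the claudin gene cldnd from 70.8 ± 7.14 to 12.1 ± 0.249 CPM. Germ plasm genes, whose products mark the germ line, fell in 10 of 17 cases and 2 (celf1 and tdrd9) rose (camera adjusted p = 0.00467; adjusted p = 0.118 with an estimated correlation), but tdrd9 lost its call in 10 of 18 refits. With DESeq2 8 fell. The members ca15b and tdrd1 fell from 107 ± 8.95 to 22.5 ± 1.30 CPM and from 98.3 ± 8.35 to 26.6 ± 0.254 CPM, and the RNA-binding protein gene celf1 rose from 102 ± 1.26 to 183 ± 2.24 CPM.

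Factors that activate the zygotic genome were split. Of 13, 8 rose and 3 fell (sox19b, eomesa and nanog) (camera adjusted p = 0.00253; adjusted p = 0.213 with an estimated correlation), but nanog lost its call in 8 of 18 refits. The pluripotency factor gene pou5f3 rose from 363 ± 21.2 to 1309 ± 27.2 CPM, and the SoxB1 genes sox3 and sox19a rose while the maternal member sox19b fell from 179.7 ± 5.11 to 54.0 ± 6.2 CPM. With library totals, 6 rose and 5 fell and the list lost its call (camera adjusted p = 0.0621; range over the alternatives 0.00101 to 0.0621).

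Ribosomal protein genes rose in 74 of 79 cases, and none fell (camera adjusted p = 3.03e-09; adjusted p = 0.118 with an estimated correlation). The median log2 fold change was 1.06 and it was 0.65 with library totals, where 50 rose and none fell, and 0.57 with the length offset, where 45 rose and none fell. The examples were rps8a, which rose from 98.5 ± 13 to 200.4 ± 13.8 CPM, rplp0 (log2 fold change 1.59 ± 0.15) and rpl7 (1.39 ± 0.14). Proteasome genes had 21 of 39 up, 2 (psme4a and psmd11a) down and 16 without a call (camera adjusted p = 0.0585; adjusted p = 0.149 with an estimated correlation). With DESeq2 10 of 41 rose, and neither fall was called. With library totals 4 rose and 4 fell, and the list was called relative to all genes (camera adjusted p = 0.0415). It was also called with upper-quartile factors, with no filter, with the length offset and without MBT A (camera adjusted p = 0.0120 in the last; range over the alternatives 0.00661 to 0.149). The members psme3 (0.67 ± 0.09), psmb5 (0.84 ± 0.13), psmb7 (1.17 ± 0.21) and psmb6 (1.72 ± 0.36) rose. Cell cycle and replication genes went both ways, with 17 of 35 up, 12 down and 6 without a call (camera adjusted p = 0.0534; adjusted p = 0.321 with an estimated correlation), and with library totals 10 were up and 15 down. The list was called with DESeq2 size factors, without the mitochondrial genes and without post-MBT B (camera adjusted p = 0.0317 in the last; range over the alternatives 0.0314 to 0.471). The G1 cyclin genes ccnd1 and ccne2 rose from 230.3 ± 9.38 to 1268 ± 5.97 CPM and from 34.3 ± 4.00 to 158 ± 3.72 CPM, cdc25b from 382 ± 20.8 to 793 ± 34.0 CPM and the replication clamp gene pcna from 172 ± 6.43 to 362 ± 9.14 CPM. With library totals the median turned below 0 for the cell cycle and chromatin modifier lists (-0.24 and -0.31). Zinc-finger and BTB genes had 33 of 107 up, 45 down and 29 without a call (camera adjusted p = 0.719; adjusted p = 0.642 with an estimated correlation). With library totals 23 were up and 57 down, and with the length offset 37 and 40. In this list znf185 rose from 9.67 ± 2.27 to 255 ± 6.81 CPM, znfl2a from 9.57 ± 1.74 to 61.8 ± 5.45 CPM and znf703 from 0.814 ± 0.528 to 24.8 ± 0.0780 CPM, while znf609a fell from 205 ± 12.7 to 66.1 ± 7.92 CPM. Of the 16 markers of differentiated tissues in the table none had enough counts to be tested, and the highest count in any library was 14.

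Of the 20 lists tested, 15 were called by camera with the preset correlation and none with an estimated one. The estimate lay below the preset value for oocyte and egg transcripts, germ plasm genes and SWI/SNF subunits. A higher correlation therefore did not remove the calls of those lists. The counts above were adjusted over all tested genes. Adjusted over the list alone, they were the same for 17 lists, with 10 FGF genes up, 23 oocyte and egg transcripts down and 17 SWI/SNF subunits up in the others. With library totals the genes up and down numbered 20 and 4 for early zygotic genes, 25 and 1 for mesendoderm, 19 and 0 for ventral, 9 and 1 for FGF and 9 and 2 for neuroectoderm genes. They were 10 and 2 for the enveloping layer, 5 and 1 for the yolk syncytial layer, 17 and 2 for gastrulation, 0 and 24 for oocyte and egg, 1 and 14 for germ plasm, 10 and 4 for other remodelers and 8 and 0 for histone genes. By fry, which asks whether a list moves one way on balance and not whether it differs from other genes, 19 lists were called. As 62.8% of all tested genes were called, this count does not set these lists apart from other genes. For the zinc-finger list fry gave the upward direction (adjusted p = 0.255, no call), against a median log2 fold change of -0.27 and a mean of -0.04.

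A further comparison asked which genes had no count in one stage. There were 17 genes at 0 in the MBT libraries with at least 10 counts in each post-MBT library, and 1, tex15, the other way. No other choice of 2 libraries against 3 gave such a gene. The 17 included the retinoic acid synthesis gene aldh1a2 (35 and 26 counts), the LIM homeobox gene lhx1b (25 and 20), fgf24 (32 and 25), the keratin-family gene cyt1 (38 and 19) and hnf4a. The counts depend on single libraries, because fewer libraries then have to be at 0 or counted: without MBT A, B or C the 17 became 26, 32 and 30, and without post-MBT A or B they became 21 and 28. The 1 gene the other way became 2 without MBT A, 3 without MBT C, 14 without post-MBT A and 10 without post-MBT B.

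Changed genes were unevenly spread over the chromosomes. On the long arm of chromosome 4 (starts beyond 27 Mb), 163 of 302 tested genes rose, 54.0% against 30.4% elsewhere (odds ratio 2.68, Fisher's exact test, adjusted p = 3.32e-15). This odds ratio was 5.39 at changes of at least 2-fold and 1.82 with DESeq2 (adjusted p = 3.02e-40 and 1.39e-06). The share that fell there was lower, 24.5% against 31.9% (odds ratio 0.691, adjusted p = 0.0286), but at changes of at least 2-fold this odds ratio was 1.16 (adjusted p = 0.440), and with DESeq2 it was 0.712 (adjusted p = 0.0821). Of the 74 that fell there, 32 were miR-430 genes, and without the miR-430 genes 42 of 269 fell. Of the 302 genes, 249 carry clone or locus names, and many genes of this arm have near-identical copies. Chromosomes 19 and 22 also had more genes that rose (36.3% and 38.1%; adjusted p = 0.0484 and 0.00656), and chromosomes 17, 18 and 24 had fewer (23.7%, 23.6% and 24.7%; adjusted p = 0.00587, 0.0110 and 0.04996). More genes fell on chromosomes 17 and 18 (38.1% and 37.9%; adjusted p = 0.0215 and 0.0475) and fewer on chromosome 22 (24.5%; adjusted p = 0.00472). As a whole, chromosome 4 had more that rose and fewer that fell (adjusted p = 2.54e-11 and 2.25e-04). With DESeq2 the rises on chromosomes 22 and 24 and the falls on chromosome 18 were no longer called (adjusted p = 0.452, 0.0821 and 0.410), while the rises on chromosome 19 were (adjusted p = 0.00953). At changes of at least 2-fold, the rises on chromosomes 19 and 24 and the falls on chromosomes 4, 17, 18 and 22 were not called. The mitochondrial rises and falls were not called there either (adjusted p = 0.340 and 0.256), nor the mitochondrial falls with DESeq2 (0.271). More rises on chromosome 25 were called at 2-fold and with DESeq2 (adjusted p = 0.0235 and 0.00345). Fewer rises on chromosome 9 were called with DESeq2 (adjusted p = 0.0209). All 15 mitochondrial genes rose, with log2 fold changes of 0.30 to 0.82; with library totals they lay between -0.11 and 0.41. Of 54 tests, 14 had an adjusted p under 0.05. Fisher's exact test counts genes as independent, which near-identical copies and mitochondrial genes need not be, so these p-values may overstate the evidence.

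**Figure D4:**
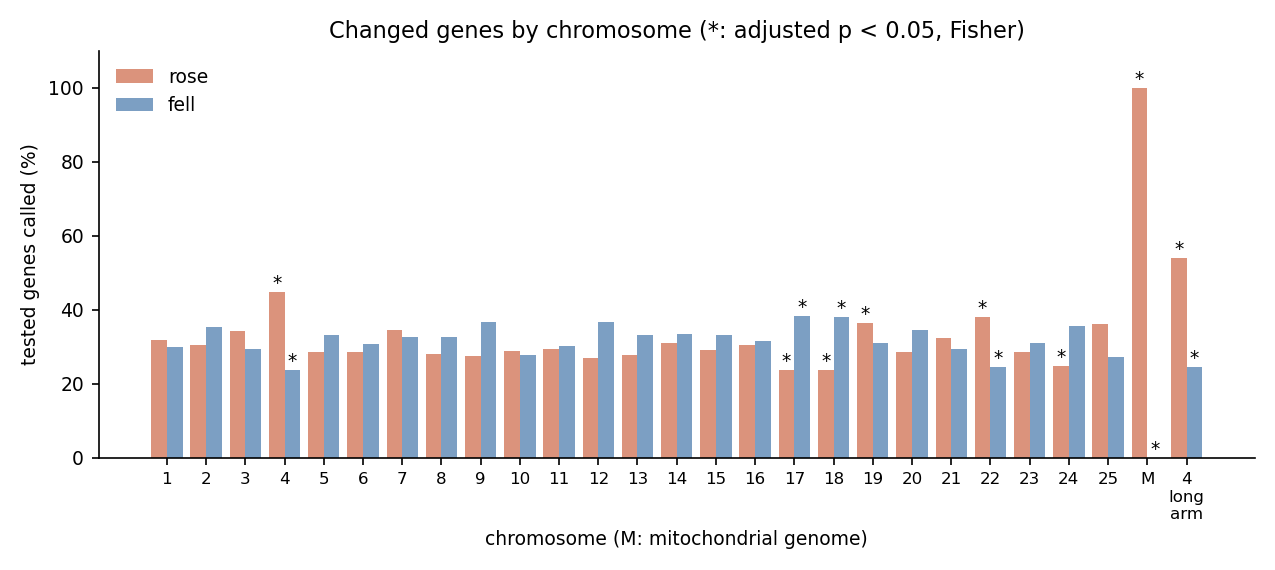
Share of tested genes that rose (orange) or fell (blue) on each chromosome (x axis), in percent; M is the mitochondrial genome, the long arm of chromosome 4 is also shown apart, and stars mark an adjusted p under 0.05 in Fisher's exact test. On the long arm 54.0% of the tested genes rose, and on M all 15 rose on the TMM scale (between -0.11 and 0.41 in log2 fold change with library totals).

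Genes that rose were shorter in the genome than genes that fell. The median genomic span was 14852 bases for genes that rose, 21919 for genes that fell and 18279.5 for genes without a call. The difference between rises and falls was -7068 bases (2-sided permutation test, adjusted p = 1e-05, the smallest it can give). Exonic length differed too, at medians of 2371, 2730 and 2271 bases, a difference of -359 between rises and falls (permutation test, adjusted p = 1e-05), with a range of -572 to -166 over the alternatives. The permutation tests treat genes as independent replicates, which they are not, so their p-values may overstate the evidence. Over 5 equal groups from the shortest to the longest span, the share that rose went from 39.6% to 21.8% and the share that fell from 24.9% to 38.0%.

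**Figure D5:**
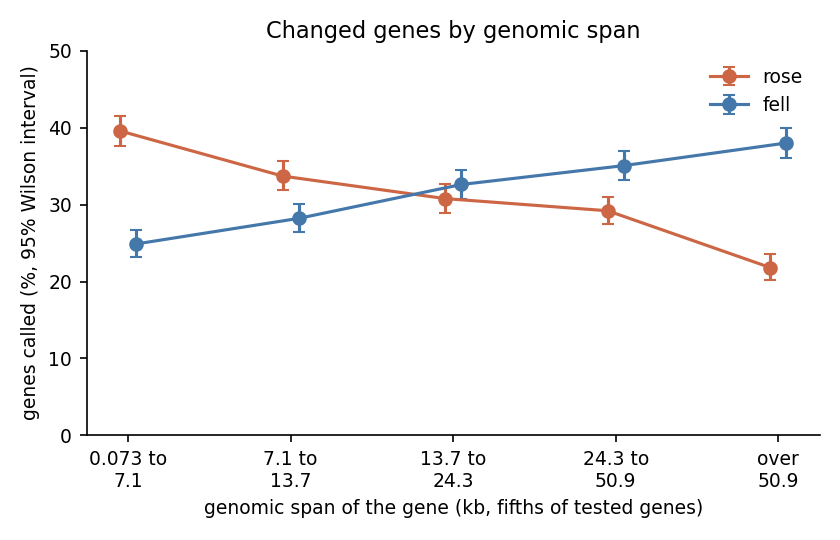
Share of tested genes that rose (orange) or fell (blue), in percent with 95% Wilson intervals, in 5 equal groups by genomic span (x axis, kb). The share that rose goes from 39.6% to 21.8% and the share that fell from 24.9% to 38.0%.

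The authors' deposited table was set beside these calls. At an adjusted p of at most 0.05, the authors' deposited table called 5673 genes, 3055 higher at 5.3 hpf and 2618 higher at 4 hpf. Of these, 5473 were tested here, and 5473 were called the same way and 0 the opposite way. In the other direction, the authors' deposited table called 72.6% of the genes called here the same way. Both sets of calls rest on the same counts, so the overlap is not an independent check. The strictest sheet of the authors' deposited table (adjusted p of at most 0.001 and at least 3-fold) held 1318 genes, of which 1303 were called in the same direction here and 15 were not tested. In the authors' deposited table the log2 ratio of 4 hpf over 5.3 hpf was -0.71 for smarca4a and 0.94 for smarca2.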

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

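The genes named here were chosen after their values were seen. The authors' deposited table holds a comparison of exon counts within genes that no comparison of gene totals uses, and it was singled out for that reason. In the authors' deposited table, 89 genes had an exon that passed a corrected p of 0.05, with the exon relatively higher at 5.3 hpf in 48 and at 4 hpf in 41. By gene total, 44 of them rose, 22 fell and 23 had no call. In the RNA-binding protein gene khdrbs1a the exon on chromosome 13, 44875913 to 44875964, had a log2 difference of 1.08 (4 hpf over 5.3 hpf; score of 301 in the authors' deposited table). In dnmbp the exon on chromosome 12, 31558665 to 31560450, had a log2 difference of -2.91 (score of 366 in the authors' deposited table). The exon of the remodeler gene atrx lies on chromosome 14, 10428373 to 10428501, and was relatively higher at 4 hpf. The gene hmga1a had a log2 difference of 1.15 on chromosome 23, 3815847 to 3815972, and lin28a one of 1.79 on chromosome 19, 15536691 to 15537219. The strongest entry of the authors' deposited table, tdrd6 (2.13), belongs to a gene whose deposited span of 7129219 bases is over 1 Mb, and 12 of the 89 genes carry LOC names. Per the file headers this is a chi-square test of exon counts between the conditions, which takes no account of the spread between libraries. No explanation of these values was tested.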

How the results depend on the processing

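Leaving out the mitochondrial genes and leaving out genes spanning over 1 Mb were chosen after seeing the data. The directions of smarca4a and smarca2 and their calls were the same in the 18 settings that refitted the data (smarca4a 0.29 to 0.88, smarca2 -1.37 to -0.79), and neither passes a minimum change of 2-fold. Called genes numbered 7537, and 3724 rose. The filter at a mean of 50 counts tests fewer genes (6147) and gave 4491 calls (2174 up, 2317 down), and calls of at least 2-fold numbered 4152 (1919 up, 2233 down). The number that rose was 2173 with library totals, 2139 with limma-trend on log2(FPKM + 1) and 2074 on log2(FPKM + 0.1), scalings that move all genes downward, and 2 called genes turned direction with library totals and 3 with the length offset. With the DESeq2 Wald test 2539 genes fell (the cause was not tested). Leaving out 1 library gave 6204 to 7383 calls (3165 to 3647 up, 3039 to 3743 down).

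With an estimated correlation camera called 0 of the 20 lists, against 15 with the preset one. The estimate was -0.002 for oocyte and egg transcripts, -0.008 for SWI/SNF subunits and -0.02 for germ plasm genes, below the preset 0.01. A higher correlation therefore did not remove those calls. For the other called lists it was above 0.01, up to 0.47 for FGF signalling. Genes varied independently in the simulation, yet the planted list went from camera adjusted p = 8.24e-57 (preset) to 0.0166 (estimated). A lost call therefore does not by itself show correlation. The replicate block, set by column position, gave 7201 calls and 15 lists. The samples share only a number, with correlations of deviations from the stage mean of -0.0251 to 0.0251. The deviations of the 2 post-MBT libraries are exact opposites, so this range is symmetric by construction. The columns were also not matched to sample numbers, so these correlations cannot decide whether libraries were paired. Of the changes in lists, 8 were gained calls (proteasome, cell cycle) and 3 were lost ones (SWI/SNF and genome activation with library totals, yolk syncytial layer with the length offset), and psme3 lost its call with limma-trend on log2(FPKM + 1). The other genes named by rule in the report kept direction and call in the settings that refitted the data and tested them, and those with smaller changes do not pass a minimum of 2-fold. Several named members that moved against their list lost their call, most often mxtx2, tdrd9 and nanog (10 of 17, 10 of 18 and 8 of 18 refits).

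Genes first counted after the MBT numbered 44 at 5 counts and 6 at 20 counts, and 21 to 32 without 1 library. Genes no longer counted numbered 10 at 5 counts, 0 at 20 counts and 2 with thinned libraries, and 1 to 14 without 1 library, since the rule then needs other counts. Chromosome tests with an adjusted p under 0.05 numbered 14, and 6 at changes of at least 2-fold, where fewer genes are called. The chromosome 4 long arm odds ratio for falls turned to 1.16 at changes of at least 2-fold (the cause was not tested) and lost its call with DESeq2 (0.712). The miR-430 genes of this arm had a median log2 fold change of -2.27, and the 2-fold test was not run without them. The difference in span between rises and falls lay between -8927 and -6143 bases in its alternatives, and that in exonic length between -572 and -166 bases, with the same direction and call. At this depth and number of libraries, the simulated test found 16 of 47 of the 1.5-fold changes. The simulated data gave 114 calls against 7537 in the real data, so this share need not carry over.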

Other observations

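The tests of gene families, the miR-430 sum, the library-totals tests of the ribosomal protein genes and smarca4a, and the setting without mitochondrial genes were chosen after the values they rest on were seen. Genes of miR-430 fell together: of 47 in the table, 46 lie on chromosome 4, 28738556 to 28754891, and of the 33 tested 32 fell. Their summed level was 1013 ± 156 CPM at the MBT (SD, n = 3) and 235 ± 30.7 post-MBT (SD, n = 2), 4.31-fold lower. The reads come from random-primed total RNA, so they are not a measure of mature microRNA, and how reads shared between the copies were counted is not known, which limits the sum as well.

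Over 57 gene families defined by the letters that open their symbols (at least 15 tested members), camera with the preset correlation called 4. These were the mir genes, whose 33 tested members are the miR-430 genes above, the rpl and rps genes, and the rbm genes. Of 30 genes named rbm, which encode proteins with RNA-binding motifs, 19 rose and 4 fell (camera adjusted p = 0.00252; median log2 fold change 0.63, 0.21 with library totals). With an estimated correlation no family was called (adjusted p = 0.499 for rbm).

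Ribosomal protein genes rose together, with a median log2 fold change of 1.06. Their transcripts are short, so a bias with exonic length is 1 possible explanation. With an offset for exonic length the median was 0.57, lower but still called by camera with the preset correlation (adjusted p = 1.09e-04), and with library totals it was 0.65. With an estimated correlation the list was not called on the TMM scale (adjusted p = 0.118). Neither the length offset nor library totals removed the rise, and length may account for part of it. Library totals are another relative scale, so they cannot decide whether scaling accounts for part or all of the rise. Reads shared with pseudogenes and the difference in stage were not tested apart.

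The opposite changes of smarca4a and smarca2 were set against scaling and mitochondrial RNA. With library totals the log2 fold change of smarca4a was 0.29, still called, and without the mitochondrial genes it was 0.72. Library totals are another relative scale, so they cannot decide whether scaling accounts for part or all of the smarca4a rise. TMM factors rest on ratios over many genes, so leaving out the few mitochondrial genes could hardly move the value. That setting by itself therefore cannot decide whether mitochondrial RNA accounts for part or all of the rise. Mitochondrial ribosomal RNA took 48.5 and 48.6% of the counts post-MBT, against 44.1, 40.2 and 48.0% at the MBT. A larger share leaves fewer counts to nuclear genes, which is the opposite of a rise. These shares argue against mitochondrial ribosomal RNA as the source of the smarca4a rise. The ratio of the 2 transcripts within a library does not depend on scaling, and it differed between the stages without overlap of libraries. What lies behind that difference was not tested, and the data hold no protein measurement.

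Genes that rose spanned less of the genome than genes that fell, and a difference in exonic length could account for it. Within 5 equal groups by exonic length, the difference in median span was -1174, -1358, -3260.5, -6324 and -19258 bases from short to long. It was -6275 on average, with the longest group weighing most, and kept its direction in each group. That group runs from 4279 to 96631 bases, so exonic length can still differ within a group. These values therefore cannot decide whether exonic length is the whole cause. No biological explanation of the difference was tested.

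Gene pairs whose symbols end in a and b, many of them copies from the fish genome duplication, were tested for a shared change. Over 801 pairs of tested genes, the Pearson r of the log2 fold changes was 0.157, where 95% of 100000 shuffled pairings lay between -0.0688 and 0.0696 (2-sided permutation p = 2e-05). Spearman's rho was 0.195. Genes are not independent replicates. Both members were called the same way in 222 pairs, where independence gives 163, and opposite ways in 120, where it gives 163. The values show a weak positive relation within pairs. Reads shared between similar copies could also give one, and how such reads were counted is not known. The shared change and shared reads were not tested apart.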
